A study of Mus musculus with 4 samples.

How the data were processed

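The data were single-cell RNA profiles of mouse lung cells in 4 libraries, 1 for each of sham, WT PNX, M3cKO PNX and Foxo1cKO PNX, the last 3 taken on day 7 after PNX. Per the labels, lungs were digested with type 1 collagenase at 2 mg per mL for 40 min at 37 °C, CD45-positive cells were removed with beads, and CD31-positive cells were then kept. Per the labels, sequencing was done on a NovaSeq 6000 and reads were mapped to mm10 with Cell Ranger 2.1.1. The submitters' notes name Cell Ranger and R 3.4.4, and the file headers carry software version 3.0.0. The deposited matrices hold raw UMI counts per gene and cell barcode (counts as the authors deposited them, whole numbers without normalization) for 32285 genes. No barcode held fewer than 500 UMIs, and the barcodes were 24 bases long. The reads themselves were not used here.

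Cells were kept with at least 500 genes detected and at most 10% mitochondrial UMIs. Doublet scores were computed per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, which took out 464, 687, 660 and 608 barcodes in sham, WT PNX, M3cKO PNX and Foxo1cKO PNX. This rule was set after Scrublet's own threshold had marked 0 barcodes in sham and 263, 79 and 257 in the others. Counts were scaled to 10000 per cell and logged, 2000 variable genes were taken, and 40 principal components and 20 neighbours fed a Leiden clustering at resolution 1 over all libraries together, without integration. Clusters were named from fixed marker lists of 20 classes when at least 3 markers of a class were among the 50 leading genes, no other class had as many, and no other class had more among the 10 leading genes, and a cluster counted as endothelial when Cdh5 reached 500 CPM and its class was endothelial or, for an unnamed cluster, no non-endothelial class had 3 markers among them. The analysis used Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM factors. A cluster with epithelial (Ager) and mural (Postn, Pdgfrb) leading genes and endothelial transcripts was kept out of the endothelium, and took 1.76%, 2.75%, 0.212% and 1.60% of the cells of the libraries in the order above.

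UMIs of endothelial cells were summed per library and expressed as CPM, with exact Poisson intervals for levels and exact conditional binomial intervals for ratios, all at 95%. Shares of cells carry exact (Clopper-Pearson) binomial intervals. Log2 ratios used a pseudocount of 5 CPM. The endothelial sums of 6065453 to 13818731 UMIs set the precision: a level of 10.7 CPM in WT PNX (Sox11, 148 UMIs) has an interval of 9.05 to 12.6. Genes were counted as 2-fold apart when the higher library reached 50 CPM, as a fixed rule of size and not as a test, because 1 library per group gives no spread between animals.

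Named genes followed a rule fixed in advance. In each comparison they were the 12 with the largest log2 ratio in each direction among genes at least 2-fold apart and in the same direction in general capillary cells and in aerocytes. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, receptor segment, sex-linked and numbered model genes were left out. So were genes more than 5 times as high in a non-endothelial class of at least 30 cells as in endothelium. Foxo1 and Rhoj were always named, as were up to 4 members of each gene list with the largest ratios at 20 CPM or more. The 22 gene lists were fixed with it. Some genes that met this rule and a gene list are not reported here. A member counted as measured at 10 CPM or more in either library and as higher or lower at 1.5-fold. Each list median was placed among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and is not a test across animals. Genes of the sex-transcript, clock, library-pairing and held-out parts were chosen after their values were seen.

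Cell cycle shares counted cells with at least 2 UMIs over Mki67, Top2a, Cdk1, Birc5, Ube2c, Cenpf, Tpx2, Nusap1, Ccnb1 and Ccna2. For thinning to 2000 UMIs, shallower cells were left out (2613, 1101, 1177 and 1260 endothelial cells in the order above). Correlations between comparisons that share a library were set beside 100 simulations of unchanged Poisson libraries and beside a random split of the WT PNX cells. Held-out values used genes chosen in a random part of the sham and WT PNX cells and measured in the rest.

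The steps from sums to counts were tested on simulated data of 18622 genes with 200 changed genes per comparison. Of 50 genes changed 2.5-fold, 50, 49 and 50 passed the 2-fold rule in the 3 comparisons, and of 50 changed 1.5-fold 0 passed. Of 3539, 3541 and 3529 unchanged genes 0 passed. A planted list of 25 genes at 1.5-fold lay at percentile 100 in each comparison, and 1 of 22 unchanged lists lay outside the central 95% range in each. A planted shared covariance of 0.0542 was recovered as 0.0491.

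The filters, gene lists, comparisons and most alternatives were set before the data were examined. These alternatives were mitochondrial limits of 5% and 20%, gene minimums of 200 and 1000, doublets kept, resolutions of 0.5 and 2, endothelial cells gated per cell, general capillary cells only, equal weight per cell, TMM scaling, classes weighted to WT PNX, a pseudocount of 1 CPM, minimums of 20 and 100 CPM, and thinned cells. Alternatives added later were Scrublet's own threshold, male-type cells only, the proliferating, interferon-led or stress-led cluster left out, and another library in place of WT PNX. Non-endothelial cells were left out of the comparisons because the CD45 beads set their number.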

Results

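Single-cell RNA sequencing was done on mouse lung cells that had been depleted of CD45-positive cells with beads and then selected for CD31, a surface marker of endothelium. The 4 libraries came from sham-operated wild-type mice (sham), wild-type mice on day 7 after PNX (WT PNX), and mice of the conditional knockouts named M3cKO and Foxo1cKO on day 7 after PNX (M3cKO PNX and Foxo1cKO PNX). PNX is the usual abbreviation of pneumonectomy, the surgical removal of lung tissue. The gene behind M3, the driver of the knockouts and the number of animals per library are not given in the sources used here. Each group was 1 library, so there were no replicates: no spread between animals, no test and no check between replicates was possible, and the 95% intervals cover counting error only.

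The matrices held 7617 cell barcodes and 16197681 UMIs (unique molecular identifiers, each counted as 1 transcript molecule) in sham, 9266 and 30445999 in WT PNX, 9080 and 26848160 in M3cKO PNX, and 8720 and 27320974 in Foxo1cKO PNX. After the cell filters 5055, 5953, 5185 and 6046 cells were kept in that order of libraries. Endothelial cells numbered 4459 in sham, 3831 in WT PNX, 2386 in M3cKO PNX and 3766 in Foxo1cKO PNX. Their summed UMIs were 9730084, 13818731, 6065453 and 12519610, and levels are given as CPM, the UMIs of a gene per 1000000 UMIs of these sums.

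The series title names Rhoj, and 1 group is named for Foxo1, so these genes were measured first. Foxo1 (ENSMUSG00000044167, GRCm38 chromosome 3, 52268336 to 52353221, plus strand), a forkhead transcription factor, was at 199 CPM (191 to 208) in sham and 211 (203 to 219) in WT PNX. It was at 189 CPM (178 to 200.2) in M3cKO PNX and 68.5 (63.9 to 73.2) in Foxo1cKO PNX, which is 3.08-fold lower than in WT PNX (2.86 to 3.33). General capillary cells held 184 CPM of Foxo1 in WT PNX and 46.2 in Foxo1cKO PNX, and aerocytes, the Car4-high capillary cells, 70.3 and 14.2. The blood cells carried along did not share the difference: B cells held 447 and 432 CPM, and T or NK cells 391 and 358. The counted reads may lie outside the deleted part of the gene, so the remaining level does not measure how many alleles were deleted.

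Within the Foxo1cKO PNX library Foxo1 differed between cells by sex transcripts. Cells with a Y-linked UMI and no Xist UMI (male-type, 569 cells) held 123 CPM (110 to 137), and cells with Xist and no Y-linked UMI (female-type, 958 cells) held 38.6 (32.8 to 45.2). The ratio was 3.18 (2.62 to 3.89) over all endothelial cells, 2.66 (1.52 to 4.70) in general capillary cells and 2.77 (1.10 to 7.35) in aerocytes. In WT PNX the same ratio was 0.961 (0.873 to 1.06). With male-type cells alone the Foxo1 log2 ratio of Foxo1cKO PNX to WT PNX was −0.79, against −1.56 over all endothelial cells. This split was chosen after its values were seen.

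Rhoj (ENSMUSG00000046768, GRCm38 chromosome 12, 75308322 to 75401456, plus strand), a small GTPase, was at 320.2 CPM (309 to 332) in sham and 278 (269 to 287) in WT PNX. It was at 338 CPM (323 to 353) in M3cKO PNX and 255 (246 to 264) in Foxo1cKO PNX. Rhoj was therefore lower in the WT PNX library than in sham, higher in M3cKO PNX than in WT PNX, and lower in Foxo1cKO PNX than in WT PNX, each by less than 1.5-fold. With at most 5% mitochondrial UMIs per cell the Rhoj log2 ratio of M3cKO PNX to WT PNX was −0.01, against 0.28. In general capillary cells alone the Rhoj log2 ratios were −0.37 for WT PNX against sham, 0.50 for M3cKO PNX and −0.23 for Foxo1cKO PNX against WT PNX, and in cells thinned to 2000 UMIs the last was −0.02.

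**Figure D1:**
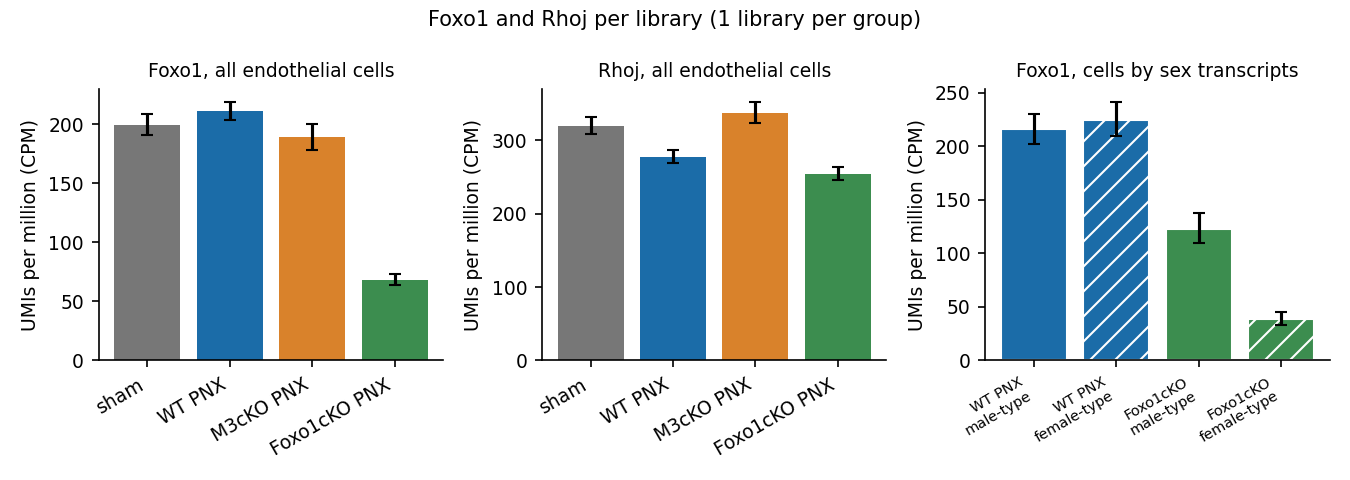
Foxo1 and Rhoj in endothelial cells of each library, in CPM (bars, 1 library each) with 95% Poisson intervals (error bars); the last panel parts WT PNX and Foxo1cKO PNX cells by sex transcripts. Foxo1 stands at 68.5 CPM in Foxo1cKO PNX against 211 in WT PNX, with 123 in male-type and 38.6 in female-type Foxo1cKO PNX cells.

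The libraries also parted in ways that their group names do not state. Xist was at 133 CPM in WT PNX and 155 in Foxo1cKO PNX endothelium and at 0 in sham and M3cKO PNX, so the first pair held cells of both sexes and the other pair male-type cells without female-type ones. Sham and M3cKO PNX also lay together, at least 2-fold above both WT PNX and Foxo1cKO PNX, in 16 endothelial genes, and at least 2-fold below both in 33. The other pairings of the 4 libraries gave 0 or 1 gene in either direction. The endothelial genes alone would part in the same way if M3cKO PNX lacked part of a PNX change. Only the sex transcripts and the genes shared with other cell types therefore bear on a pairing apart from the groups. Of the 16 genes 5 were higher, by at least 1.5-fold, in B cells and in T or NK cells of the same pair of libraries too (Rab6b, Rnaset2b, H2-Eb1, Hspa1b and Hspa1a). Of the 33 genes 5 were lower there (Pf4, Gbp9, Eln, Gdpd3 and Fbln5). Sham held only 85 B cells and 57 T or NK cells, so its low values in these cells rest on few UMIs. Rab6b, Pf4, Eln and Fbln5 stood lower in B cells and in T or NK cells than in endothelium, so free RNA carried along can account for Pf4, Eln and Fbln5 there. Rab6b in T or NK cells was at 31.0 CPM in sham and 28.0 in M3cKO PNX, against 66.6 and 52.9 in endothelium. In the same M3cKO PNX T or NK cells Eln was at 4.0 CPM and Fbln5 at 0, against 342 and 129 in endothelium. This argues against free RNA from endothelium as the whole source of Rab6b in T or NK cells. Rnaset2b, at 104 and 79.8 CPM in B cells of sham and M3cKO PNX against 24.1 in WT PNX and 24.6 in Foxo1cKO PNX, Gbp9 and Gdpd3 were at about the endothelial level or above it in the libraries where they were high. Hspa1b, an inducible heat shock chaperone, was at 1899 CPM in sham B cells, 475 in M3cKO PNX, 17.6 in WT PNX and 17.4 in Foxo1cKO PNX (immunoglobulin-secreting cells left out). Sham with M3cKO PNX and WT PNX with Foxo1cKO PNX thus form pairs that the comparisons of sham and of M3cKO PNX with WT PNX cross.

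The comparison of WT PNX with sham asks what PNX changes in the endothelium of wild-type lungs. Cell division genes stood out: Mki67, a marker of cycling cells, was at 278 CPM in WT PNX and 17.7 in sham (15.7-fold, 13.5 to 18.5), and Top2a, a topoisomerase used in chromosome segregation, at 222 and 13.2 (16.8-fold, 14.1 to 20.3). The mitotic genes Prc1, Ube2c, Ckap2, Tpx2, Cenpf, Cdk1 and Ccna2 and the replication factor gene Pclaf were between 10.4-fold and 15-fold higher. All 33 measured members of the cell cycle G2 and M phase list and 23 of 25 of the S phase list were at least 1.5-fold higher in WT PNX, with median log2 ratios of 2.42 and 1.32. The S phase members included Rrm2, a subunit of ribonucleotide reductase, at 92.6 CPM against 12.5. Between 66.8% and 92.5% of the WT PNX UMIs of these named cell cycle genes lay in the proliferating cluster, and weighting the endothelial classes of both libraries to the WT PNX composition, which holds that cluster equal, brought the G2 and M phase median to −0.03. Within general capillary cells 12 of 13 G2 and M phase genes (median 1.35) and 26 of 28 S phase genes (median 1.65) were at least 1.5-fold higher in WT PNX.

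Cells with at least 2 UMIs over 10 cell cycle genes made up 12.4% of endothelial cells in WT PNX (474 of 3831, exact binomial interval 11.3 to 13.5) and 0.695% in sham (31 of 4459, 0.473 to 0.985). The share was 3.90% in M3cKO PNX (93 of 2386, 3.16 to 4.75) and 8.34% in Foxo1cKO PNX (314 of 3766, 7.47 to 9.27). In female-type cells alone the share was 7.77% (6.15 to 9.66) in WT PNX and 10.3% (8.48 to 12.4) in Foxo1cKO PNX, with overlapping intervals. In male-type cells it was 20.5% and 11.4%. The higher share of WT PNX was thus not seen in female-type cells. The median depths were 2641.5 and 3050.5 UMIs in female-type and 4262.5 and 3474 in male-type cells, and this split was not thinned. After every cell was thinned to 2000 UMIs the shares were 0.975%, 12%, 5.29% and 8.58% in the order sham, WT PNX, M3cKO PNX and Foxo1cKO PNX. The median depths of the endothelial cells were 1805, 2699, 2019.5 and 2497.5 UMIs in the same order. With at most 5% mitochondrial UMIs per cell the shares were 1.13% in sham, 5.77% in WT PNX (4.27 to 7.60), 3.75% in M3cKO PNX (2.37 to 5.63) and 4.26% in Foxo1cKO PNX, so the intervals of WT PNX and M3cKO PNX overlapped.

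**Figure D2:**
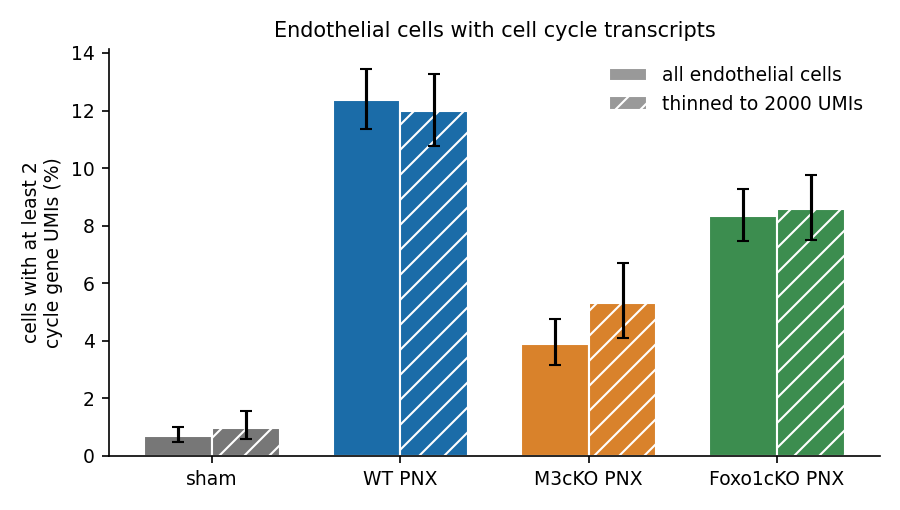
Percent of endothelial cells of each library with at least 2 UMIs over the 10 cell cycle genes (bars, 1 library each) with exact 95% binomial intervals (error bars), for all cells and for cells thinned to 2000 UMIs (hatched). WT PNX stands at 12.4% and 12%, and sham at 0.695% and 0.975%.

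Matrix, adhesion and lipid genes also lay higher in the WT PNX library. Of 27 measured extracellular matrix and basement membrane genes 14 were at least 1.5-fold higher and 1 lower than in sham (median 0.63), among them Fbln5, an elastic fibre protein, at 484 against 117 CPM, Col15a1 at 303 against 74.0 and Col18a1 at 138 against 36.3. The mesenchymal transition list had 9 of 14 members higher and 0 lower (median 0.73), with Col3a1 at 51.4 against 12 CPM and Acta2 at 28.9 against 10.8. Inflammatory adhesion and chemokine genes were higher in 13 and lower in 3 of 26 (median 0.47): Ackr1, a chemokine-binding receptor of venules, was at 131 against 10.8 CPM (12.2-fold, 10.0 to 15), Selp (P-selectin) at 345 against 86.7 and Sele (E-selectin) at 30.5 against 5.14. Within classes that median was 0.09 in general capillary cells, −0.26 in aerocytes and 0.23 in venous cells, and venous cells took a larger share of the WT PNX endothelium. Lipid handling genes were higher in 9 and lower in 4 of 28 (median 0.19), with Fabp4 at 533 against 209.7 CPM. Eln, Col3a1, Acta2, Fn1, S100a6, Ptgs2, Il6 and Thbs1 were more than 5 times as high in a non-endothelial class as in endothelium, so free RNA or carry-over can add to their counts. Col3a1, Fn1, Acta2 and S100a6 were the mesenchymal members with the largest ratios. Fibroblasts made up 1.35% of sham and 2.59% of WT PNX cells, and 28% of the WT PNX Acta2 UMIs lay in 1 cell.

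Antigen presentation and capillary identity genes were among those lower in WT PNX. Of 22 antigen presentation genes 14 were at least 1.5-fold lower and 0 higher (median −0.83): the class I genes H2-Q6 and H2-T23 were at 156 and 340.3 CPM against 541 and 1124 in sham, the class II chaperone genes H2-DMa at 7.09 against 41.7 and H2-DMb1 at 30.0 against 97.9, and H2-Eb1 at 45.4 against 537. H2-Eb1 also parted sham and M3cKO PNX from the other libraries in B cells. The capillary identity list had 8 of 20 members lower and 0 higher (median −0.48), with Cyp4b1 at 331 against 1069 CPM, Fibin, an aerocyte marker, at 55.8 against 173 and Emp2 at 526 against 1065. In general capillary cells alone that median was 0.02. Sox11, a transcription factor, was at 10.7 against 159.8 CPM (14.9-fold lower, 12.6 to 17.8), and Rab6b, Cyp26b1, Ifi208 and Rnaset2b were between 3.89-fold and 10.3-fold lower. Ifi204, an interferon-inducible gene, was higher at 70.9 against 1.75 CPM (40.6-fold, 25.2 to 70.0). Sox11 and Ifi204 set the WT PNX library apart from all the others: Sox11 was at 127 CPM in M3cKO PNX and 101 in Foxo1cKO PNX, and Ifi204 at 1.32 and 3.51. Prg2, at 0.434 against 175 CPM, came from 1 sham cell with 1684 of its 1699 UMIs.

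In total 106 genes were at least 2-fold higher in WT PNX than in sham and 66 lower, of 4023 with at least 50 CPM. The higher genes numbered 65 in general capillary cells alone, 67 with at most 5% mitochondrial UMIs, 68 without the proliferating cluster and 42 with classes weighted to WT PNX, and the lower ones 109 in male-type cells alone. Pro-fibrotic and angiocrine factors, which the title names, had 15 of 42 members higher and 3 lower with a median of 0.11, inside the central 95% of matched random lists (percentile 83.8); Ptgs2, a prostaglandin synthase, was at 221 against 53.2 CPM, with 94.6% of its WT PNX UMIs in venous cells and a log2 ratio of −0.04 in general capillary cells alone. The FOXO list had 0 of 30 higher and 4 lower (median −0.14), including Txnip at 386 against 1034 CPM and Tsc22d3 at 105 against 247. Endothelial junction genes had a median of −0.24, with Cldn5, a tight junction protein, at 811 against 1734 CPM, and 7 of 34 interferon response genes were lower and 2 higher (median −0.14, but 0.01 with at most 5% mitochondrial UMIs). Oxidative phosphorylation had a median of 0.17 with 1 of 44 higher and 2 lower.

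Lists with medians inside the central 95% range of matched random lists in WT PNX against sham were m6A RNA methylation (0.02), tip cell and sprouting (0.04), Notch, BMP and TGF-beta (−0.11), shear stress (−0.08), immediate early and stress (0.06), glycolysis and hypoxia (0.10), p53 and apoptosis (0.02) and Hippo and YAP (0.08).

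**Figure D3:**
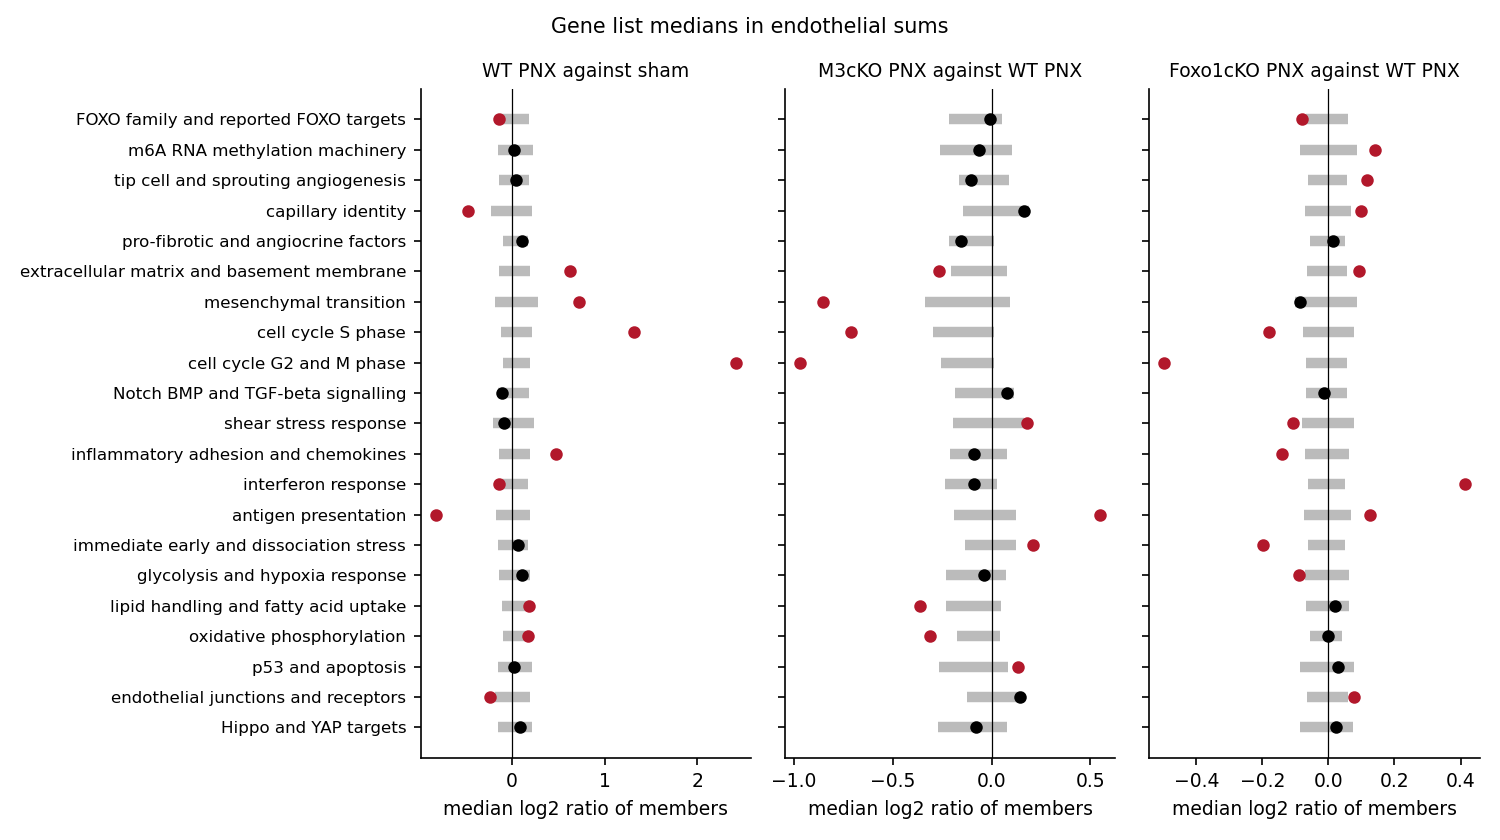
Median log2 ratio of the members of the gene lists reported (dots) in the 3 comparisons, with the central 95% range of 10000 random lists matched on size and expression (grey bars); red dots lie outside the range. The G2 and M phase median is 2.42 in WT PNX against sham, −0.97 in M3cKO PNX against WT PNX and −0.50 in Foxo1cKO PNX against WT PNX.

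The comparison of M3cKO PNX with WT PNX asks what the knockout named M3 changes in the endothelium after PNX. The heat shock chaperone genes Hspa1b and Hspa1a were higher in M3cKO PNX: Hspa1b was at 1368 against 138 CPM (9.93-fold, 9.45 to 10.4) and Hspa1a at 663 against 83.5 (7.94-fold, 7.44 to 8.49). The circadian clock genes Dbp, Nr1d1, Tef and Nr1d2 were also higher, with Dbp at 62.3 against 3.47 CPM (17.9-fold, 13.3 to 24.8), Nr1d1 at 153 against 12.4 (12.3-fold, 10.4 to 14.5), Tef at 65.8 against 8.03 and Nr1d2 at 96.0 against 19.4. Timp3, an inhibitor of matrix metalloproteinases, was at 3623 against 625 CPM (5.80-fold, 5.66 to 5.95) and had a UMI in 2096 of 2386 M3cKO PNX endothelial cells. The kinase gene Map3k6 was at 285 against 52.2 CPM, Inhbb, an activin subunit, at 66.8 against 13.3 and Fkbp14 at 140.5 against 32.9. Sox11 (127 against 10.7) and Rab6b (52.9 against 6.44) were higher in M3cKO PNX as they were in sham.

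Cell division genes lay lower in the M3cKO PNX library. Of 33 G2 and M phase genes 31 were at least 1.5-fold lower and 0 higher (median −0.97), with Top2a at 74.0 against 222 CPM and Mki67 at 107 against 278, and within general capillary cells 8 of 13 were lower (median −0.72). Of 25 S phase genes 21 were lower (median −0.71), with Rrm2 at 30.8 against 92.6 CPM. Among the other genes that were lower, Ackr1 was at 6.27 against 131 CPM (21-fold lower, 15.2 to 29.7), Fabp4, a fatty acid binding protein, at 80.5 against 533, Adgrg6 at 34.8 against 179 and Fbln5 at 129 against 484. Pdlim3, Pgm5, Tmem45a, Car8, Ccdc80 and Bpgm were between 4.65-fold and 19.9-fold lower. Most WT PNX UMIs of Pgm5, Tmem45a and Car8 (80.3% to 83.5%) came from venous cells, and Ifi204 was at 1.32 against 70.9 CPM in M3cKO PNX as in the other libraries.

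By list, the mesenchymal transition genes were lower in 9 of 14 (median −0.85), with Tagln at 9.73 against 48.9 CPM, and extracellular matrix genes lower in 12 and higher in 4 of 28 (median −0.26), with Fbln2 at 49.0 against 173. Tagln, Col3a1, Acta2 and Fn1, the mesenchymal members with the largest ratios, were more than 5 times as high in a non-endothelial class as in endothelium, and fibroblasts made up 2.59% of WT PNX and 1.02% of M3cKO PNX cells, so free RNA or carry-over can add to this difference. Within general capillary cells 5 of 10 mesenchymal members were lower (median −0.58). Lipid handling genes were lower in 11 and higher in 2 of 28 (median −0.36), with Scd2, a fatty acid desaturase, at 35.1 against 128 CPM. Oxidative phosphorylation genes were lower as a group by a small amount (median −0.31, 3 of 44 at least 1.5-fold lower and 0 higher), with Ndufa6 at 97.1 against 181 CPM. Antigen presentation genes were higher in 10 and lower in 3 of 22 (median 0.55), with H2-Q6 at 459 against 156 CPM and H2-Q7 at 1024 against 396. The immediate early and stress list was higher in 11 and lower in 1 of 33 (median 0.21), and its median was −0.06 without the cluster led by Atf3, Hspa1a and Egr1. The p53 and apoptosis list had a median of 0.14, with the survival gene Bcl2l1 at 209.1 against 64.1 CPM and Fas at 226 against 101, and the shear stress list 0.18 with a mean of −0.06.

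Pro-fibrotic and angiocrine factors parted in M3cKO PNX, with 9 of 43 at least 1.5-fold higher and 14 lower (median −0.15, percentile 17.6). Timp3 and Inhbb led the higher members, and Ptgs2 at 35.9 against 221 CPM and Bmp4 at 59.2 against 208 the lower ones. FOXO targets had 7 of 31 higher and 1 lower (median −0.01), with Tsc22d3, a glucocorticoid-induced gene, at 376 against 105 CPM, Txnip at 864 against 386 and the cytokine receptor gene Il6st at 456 against 1106. The medians of the other lists were −0.06 for m6A RNA methylation, −0.10 for tip cell and sprouting, 0.16 for capillary identity, 0.08 for Notch, BMP and TGF-beta, −0.09 for inflammatory adhesion, −0.09 for interferon response, −0.04 for glycolysis and hypoxia, 0.14 for endothelial junctions and −0.08 for Hippo and YAP. These 9 medians lay inside the central 95% of matched random lists.

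In M3cKO PNX 91 genes were at least 2-fold higher than in WT PNX and 97 lower, of 3944 with at least 50 CPM. The median log2 ratio of all 8974 genes at 10 CPM or more was −0.12, and with TMM scaling 123 genes were higher and 70 lower. With sham in place of WT PNX as the reference 58 genes were lower. M3cKO PNX and WT PNX also differed in the sex of the cells and in the genes that part the libraries in B cells and T or NK cells, as given above.

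Genes chosen as 2-fold apart between WT PNX and sham were then followed in both knockouts, using cells of sham and WT PNX that had not been used to choose them. These cells came from the same 2 libraries, so the split takes out counting error of the choice only. Any other difference between the 2 libraries stays in, and the WT PNX values are no independent check. The 81 genes higher after PNX had median log2 ratios to sham of 1.52 in held-out WT PNX cells, 0.71 in M3cKO PNX and 1.46 in Foxo1cKO PNX. At least 1.5-fold higher than sham were 80 of them in WT PNX, 43 in M3cKO PNX and 77 in Foxo1cKO PNX. Without the members of both cell cycle lists the 57 that remained, which still held genes of cell division such as Racgap1 and Smc2, had medians of 1.40, 0.50 and 1.25. The 51 genes lower after PNX had medians of −1.23, −0.46 and −1.14. M3cKO PNX, which like sham held no female-type cells and high heat shock transcripts, thus stood nearer to sham on these genes than Foxo1cKO PNX did. These genes were followed only after the comparisons had been seen.

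**Figure D4:**
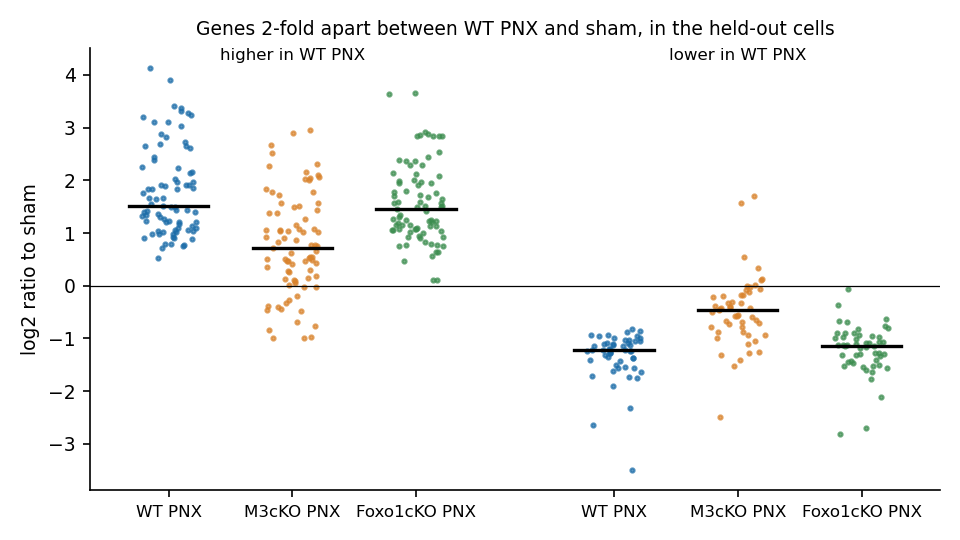
Log2 ratio to held-out sham cells of the 81 genes higher and the 51 genes lower in WT PNX (dots, genes) with their median (lines), in held-out WT PNX cells and in both knockout libraries. The medians are 1.52, 0.71 and 1.46 for the higher genes and −1.23, −0.46 and −1.14 for the lower ones.

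The comparison of Foxo1cKO PNX with WT PNX asks what the Foxo1 conditional knockout changes in the endothelium after PNX. Interferon response genes were higher in Foxo1cKO PNX, 12 of 35 by at least 1.5-fold and 0 lower (median 0.41): Isg15, a ubiquitin-like protein induced by interferon, was at 61.7 against 25.5 CPM (2.41-fold, 2.13 to 2.75), Ifit3 at 51.2 against 24.2 and Ifit1 at 134 against 68.0. The median was 0.64 in male-type cells and 0.29 in female-type cells. G2 and M phase genes were lower, 7 of 33 by at least 1.5-fold and 0 higher (median −0.50), with Top2a at 137 against 222 CPM and Anln at 28.8 against 50.1. That median was −0.43 in male-type cells and 0.07 in female-type cells, and within WT PNX it was 0.91 between male-type and female-type cells. Sox11 was at 101 against 10.7 CPM (9.43-fold, 7.95 to 11.3), Ifi208 at 70.3 against 21.8, Mndal at 167 against 71.9 and Hebp1 at 66.5 against 30.0. Lower in Foxo1cKO PNX were Ifi204 at 3.51 against 70.9 CPM (20.2-fold, 14.9 to 28.0), Ackr1 at 29.0 against 131 (4.53-fold, 4.05 to 5.09) and Foxo1 itself. Of the 7 genes at least 2-fold higher, 3 (Ifi208, Mndal and Sox11) were 2-fold lower in WT PNX than in sham and 2 (Gdpd3 and Hebp1) higher. Of the 7 lower genes 5 (Ackr1, Fosb, Gm8797, Ifi204 and Nrgn) were 2-fold higher in WT PNX than in sham. A shift of the WT PNX library itself would move the ratios of both comparisons in opposite directions. For Ifi208, Mndal, Sox11 and the 5 lower genes it therefore cannot be told apart from the Foxo1 knockout. Gdpd3 and Hebp1 were higher in both comparisons, which such a shift alone would not give. Fosb and Nrgn were more than 5 times as high in a non-endothelial class as in endothelium, so carry-over can add to them too.

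In total 7 of 3909 genes were at least 2-fold higher and 7 lower in Foxo1cKO PNX, with Sox11, Ifi208, Mndal, Isg15, Hebp1, Ifi204, Ackr1 and Foxo1 among them. With at most 5% mitochondrial UMIs 12 were higher and 13 lower, in male-type cells alone 23 were higher, with every cell weighing the same 3 were higher, and without genes high in non-endothelial classes 3 were lower. FOXO targets had 0 of 30 higher and 2 lower (median −0.08), Foxo1 among the lower, with Foxo3 at 30.6 against 24.2 CPM and Ccng2 at 39.9 against 27.4. Of the pro-fibrotic and angiocrine factors 3 of 44 were higher and 3 lower (median 0.01). Among the higher were Igfbp3 at 58.5 against 10.1 CPM, with 88.3% of its UMIs in an unnamed endothelial cluster led by Fabp4, Prnd and C1qtnf9, and Inhba at 21.9 against 1.23, with 44.5% of its UMIs in 1 cell. Inflammatory adhesion genes had 0 higher and 3 of 25 lower (median −0.14), with Selp at 219 against 345 CPM. That median was 0.16 in male-type cells. S phase genes had 1 of 25 lower (median −0.18), and their median in general capillary cells alone was 0.025.

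The immediate early and stress list had a median of −0.20 in Foxo1cKO PNX against WT PNX, with Hspa8 at 1025 against 1532 CPM. Antigen presentation stood at 0.13, tip cell and sprouting at 0.12, capillary identity at 0.10, with Fibin at 88.4 against 55.8 CPM, extracellular matrix at 0.09, endothelial junctions at 0.08 and shear stress at −0.11. The m6A RNA methylation list stood at 0.14, with Mettl3 at 14.7 against 25.2 CPM, and its median was −0.06 in male-type cells. In general capillary cells alone the extracellular matrix median was −0.01, and with classes weighted to WT PNX the capillary identity median was −0.01. The medians were −0.08 for mesenchymal transition, −0.01 for Notch, BMP and TGF-beta, −0.09 for glycolysis and hypoxia, 0.02 for lipid handling, −0.001 for oxidative phosphorylation, 0.03 for p53 and apoptosis and 0.02 for Hippo and YAP. Among these 7, glycolysis and hypoxia alone lay outside the central 95% of matched random lists.

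Endothelial classes took different shares of the endothelium in the 4 libraries. Proliferating cells made up 0.426% in sham (exact binomial interval 0.257 to 0.665), 6.53% in WT PNX (5.76 to 7.35), 2.35% in M3cKO PNX (1.78 to 3.04) and 4.25% in Foxo1cKO PNX (3.63 to 4.94). General capillary cells made up 57.5%, 36.9%, 65.4% and 33.3% in that order. An unnamed cluster led by Ntrk2, with 6 general capillary markers among its leading genes, made up another 6.77%, 13.4%, 3.39% and 12.7%, and counting it as general capillary would narrow these gaps. The named general capillary cells lay mostly in a cluster led by Sox11 and Glp1r in sham and M3cKO PNX. In WT PNX and Foxo1cKO PNX their largest cluster was led by Pcdh17, with 16.4% and 14.3% of the endothelium. That cluster made up 1.64% in sham and 2.14% in M3cKO PNX. A cluster led by the stress genes Atf3 and Hspa1a made up 12.9% in sham, 12.3% in WT PNX, 22.5% in M3cKO PNX and 8.74% in Foxo1cKO PNX. Aerocytes made up 16.1%, 16.2%, 9.89% and 18.7%, arterial cells 4.15%, 8.59%, 2.77% and 9.69%, and venous cells 8.14%, 12.7%, 9.77% and 12.5%. Lymphatic cells made up 3.57%, 1.88%, 1.84% and 1.91%.

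Both knockouts were set against the same WT PNX library, which ties their ratios together. Over 4187 genes the log2 ratios of M3cKO PNX and Foxo1cKO PNX to WT PNX had a Pearson correlation of 0.209 and a Spearman correlation of 0.140 across genes, which are not independent replicates. Simulated unchanged libraries that share WT PNX gave a Pearson correlation of 0.377 with a covariance of 0.00138, and the observed covariance was 0.0200. With WT PNX cells split at random so that each knockout had its own part, the correlation was 0.147. Of the 91 genes higher in M3cKO PNX and the 7 higher in Foxo1cKO PNX among the 4189 with at least 50 CPM in any of the 4 libraries, 2 were shared, Hebp1 and Sox11, where 0.152 would be by the product of the counts, which leaves the shared WT PNX library out of account. Of the 100 and 7 lower ones 6 were shared (Ackr1, Fosb, Gm8797, Ifi204, Nrgn and Sftpc), where 0.167 would be by that product. Carry-over can add to Fosb and Nrgn, as given above, and to Sftpc. Sftpc led an alveolar epithelial cluster with 46 cells in WT PNX, 4 in M3cKO PNX and 12 in Foxo1cKO PNX. After the exclusions used for named genes 3 lower genes remained in Foxo1cKO PNX. Of the shared genes only Ackr1 and Ifi204 were among them, so this overlap is mostly not clear endothelial signal. Simulated unchanged libraries that share WT PNX had 0 shared genes in either direction, which covers counting error only, while any shift of the WT PNX library itself enters both comparisons.

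WT PNX is also the numerator against sham and the denominator for both knockouts. The correlation of WT PNX against sham with M3cKO PNX against WT PNX was −0.588 (simulated −0.350, covariance −0.140 against −0.00137, split WT PNX −0.560), and with Foxo1cKO PNX against WT PNX −0.342 (simulated −0.441, covariance −0.0334 against −0.00138, split −0.257). Among the same 4189 genes 111 were higher in WT PNX than in sham and 100 lower in M3cKO PNX, and 67 were shared, where 2.65 would be by the product of the counts and 0 in the simulated unchanged libraries. Pairs of comparisons without a common library gave 0.448 for WT PNX against sham with Foxo1cKO PNX against M3cKO PNX, 0.535 for Foxo1cKO PNX against sham with WT PNX against M3cKO PNX, and −0.154 for M3cKO PNX against sham with Foxo1cKO PNX against WT PNX. Both positive values set WT PNX and Foxo1cKO PNX against sham and M3cKO PNX, the pairs that also differ in sex and heat shock transcripts. They cannot part PNX or the M3 knockout from that pairing.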

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

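Tests chosen only after the result was seen were the one on genes shared by other cell types for M3cKO PNX, the share of antigen-presenting cells, the T or NK cell values of the antigen presentation genes, H2-Eb1 alone, and the counts of the same genes that stayed apart. Non-endothelial clusters and sex transcripts were not used in the comparisons, and each of the following stood above its sham level.

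Xist was at 133 CPM (127 to 140) in WT PNX and 155 CPM (148 to 162) in Foxo1cKO PNX endothelium, and at 0 in sham, where 3 UMIs would be 0.308 CPM. A T-cell cluster led by Lef1 and Dusp10 made up 8.55% of WT PNX cells (509 of 5953) and 11.3% of Foxo1cKO PNX cells (685 of 6046), against 0.554% in sham and 3.45% in M3cKO PNX. A cluster led by Icos and Ctla4, genes of activated T cells, made up 17.4% of M3cKO PNX cells (900 of 5185) against 0.514% in sham. It made up 2.02% in WT PNX and 3.36% in Foxo1cKO PNX. Neutrophils led by S100a9 and S100a8 made up 3.93% of M3cKO PNX cells and macrophages led by C1qb and C1qc 4.09%, each against 0.0198% in sham. In WT PNX and Foxo1cKO PNX neutrophils stood at 1.18% and 1.09%, and these macrophages at 0.504% and 0.281%. Sham held few non-endothelial cells of any kind, with 88.2% of its cells endothelial against 64.4% in WT PNX, 46.0% in M3cKO PNX and 62.3% in Foxo1cKO PNX. Cells led by Jchain and Igha, as in plasma cells, made up 2.01% of M3cKO PNX cells (104 of 5185) and 0 of 5055 in sham, which allows up to 0.0729%. The CD45 bead step removes such cells, so these shares also depend on how far it went.

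The 187 genes at least 2-fold apart between M3cKO PNX and WT PNX endothelium, sex genes aside, were weighed first. In male-type cells alone 232 genes were apart, with classes weighted to WT PNX 146 and without the stress-led cluster 175, and 164, 135 and 164 of the 187 stayed at least 2-fold apart in the same direction, which argues against sex, class composition or that cluster as the whole source. Of those genes that B cells or T or NK cells also express, the median log2 ratio in the endothelial direction was 0.82 in B cells (55 genes, 1.33 in endothelium) and 1.04 in T or NK cells (46 genes, 1.32 in endothelium). This is consistent with a difference that reaches other cell types of the library, such as handling, time of collection or strain, as a candidate source of part of the pattern. The M3 knockout itself stays open, since it came with 1 library.

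The interferon response list was higher in Foxo1cKO PNX than in WT PNX endothelium by a median log2 ratio of 0.41. Without the interferon-led cluster the median was 0.41 (0.409) and in male-type cells alone 0.64, which argues against that cluster or the mix of sexes as its whole source. In B cells the median was 0.52 (29 genes) and in T or NK cells 0.38 (35 genes), so a change shared across the library may account for it. An effect of the Foxo1 knockout stays open and was not tested apart from the library. In Foxo1cKO PNX male-type cells held more Foxo1 (123 CPM) than female-type cells (38.6). Their list median against WT PNX was still the larger, 0.64 against 0.29 in female-type cells. An effect that grows with Foxo1 loss would run the other way. Sex and animals may differ between these cells too, so this does not decide it.

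Antigen presentation genes were lower in WT PNX than in sham endothelium by a median log2 ratio of −0.83. The median was −0.95 in male-type cells alone. Antigen-presenting cells made up 2.65% of sham cells and 13.1% of WT PNX cells, the wrong way round for free RNA. This share cannot settle it, because the CD45 beads set it and it does not measure free RNA. H2-Eb1 and Cd74 were more than 5 times as high in a non-endothelial class as in endothelium. T or NK cells held more of both in sham, at 116 and 93.1 CPM, than in WT PNX, at 12.5 and 38.2. For the class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74 the median was 0.21 in B cells against −2.00 in endothelium, which argues against a haplotype difference as the source for this set as a whole, although it was −1.08 in T or NK cells, which held little class II RNA (H2-Aa at 147 CPM in sham, against 8436 in B cells). For the class I genes H2-Q6, H2-Q7 and H2-T23 the medians were −0.14 in B cells and −0.67 in T or NK cells against −1.71. The B-cell median, at 0.083 of the endothelial one, met the bar set beforehand against a haplotype difference. The T or NK median, looked at afterwards, was at 0.395 of it. H2-Eb1 alone was at −1.31 and −2.79 against −3.43. For these genes a haplotype difference cannot be told apart from a change in endothelium because the other cell types share the difference in part. In male-type and female-type cells H2-Eb1 was at 12.3 and 79.1 CPM in WT PNX and at 68.7 and 10.8 in Foxo1cKO PNX. H2-Aa was at 231 and 342 CPM, and at 304 and 391. All these cells had PNX and the order for H2-Eb1 turned round, so neither PNX nor sex alone accounts for that gap. Whether it lies between animals was not tested. The sham values of all these sets rest on 85 B cells and 57 T or NK cells. H2-D1 also paired the libraries outside endothelium, at 5680 CPM in WT PNX and 5619 in Foxo1cKO PNX T or NK cells against 3469 in sham and 3390 in M3cKO PNX, and PNX stays among the open explanations.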

How the results depend on the processing

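Alternatives added after the data were seen were male-type cells only, the proliferating, interferon-led or stress-led cluster left out, Scrublet's own threshold and another library in place of WT PNX. Of 122 gene counts under other settings 104 stayed within 1.5 times the main count, and of the list medians 1002 moved by no more than 0.5 times the width of the central 95% range of their random lists, 111 moved more and 9 reversed. Of the log2 ratios of single genes 2843 stayed inside their counting interval, 2189 moved out of it and 13 reversed, and of the shares 156 stayed inside and 144 moved out. Of the correlations 5 stayed and 4 moved. Depth limits genes near 10 CPM. Unless stated, the cause was not tested.

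With at most 5% mitochondrial UMIs, 67 genes were higher in WT PNX than in sham, and 12 higher and 13 lower in Foxo1cKO PNX than in WT PNX. The log2 ratios were −0.012 for Rhoj and 0.021 for Hmmr in M3cKO PNX, −1.84 for Foxo1 and −0.26 for Rhoj in Foxo1cKO PNX, and the interferon response median was 0.011 in WT PNX against sham. Cells with at least 2 UMIs over the cell cycle genes made up 1.13% in sham, 5.77% in WT PNX, 3.75% in M3cKO PNX and 4.26% in Foxo1cKO PNX.

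With at least 1 UMI in place of 2, which by construction admits more cells, the cycle shares were 2.31%, 21.2%, 7.00% and 13.4% in sham, WT PNX, M3cKO PNX and Foxo1cKO PNX. With at least 3 UMIs they were 10.2%, 3.14% and 7.25% in the PNX libraries, with at least 1000 genes per cell 14.1%, 5.92% and 9.94%, and in male-type cells 20.5%, 5.17% and 11.4%. In cells thinned to 2000 UMIs the M3cKO PNX share was 5.29%, and the Rhoj log2 ratio was −0.29 in WT PNX against sham and −0.023 in Foxo1cKO PNX.

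With classes weighted to WT PNX, 42 genes were higher in WT PNX than in sham, Rhoj was at −0.12 and Foxo1 at −1.44 (Foxo1cKO PNX). The G2 and M phase median was −0.032, with Ube2c at −0.16, Tpx2 at −0.0007, Cenpf at −0.14, Cdk1 at −0.24, Ccna2 at −0.37 and Rrm2 at −0.73, because the weighting holds the proliferating class equal. Capillary identity was at −0.0075 in Foxo1cKO PNX. Without the proliferating cluster 68 genes were higher in WT PNX than in sham.

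In general capillary cells only, 65 genes were higher in WT PNX than in sham, where Rhoj was at −0.37, Chst1 at 0.47, Ptgs2 at −0.038, Cyp1b1 at −0.060 and capillary identity at 0.024. In M3cKO PNX Rhoj was at 0.50, Sele at 0.12 and Rsad2 at −0.052. In Foxo1cKO PNX Foxo1 was at −1.89, Rhoj at −0.23, extracellular matrix at −0.0054 and S phase at 0.025. The correlation of the knockouts was 0.142, and of WT PNX against sham with each −0.549 and −0.223.

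In male-type cells only, 109 genes were lower in WT PNX than in sham and 23 higher in Foxo1cKO PNX, with Rhoj at 0.20 (M3cKO PNX) and Foxo1 at −0.79. The m6A median was −0.063 and the inflammatory adhesion median 0.16 in Foxo1cKO PNX. With doublets kept or Scrublet's own threshold Foxo1 was at −1.48, and with TMM scaling, which shifts all genes of a comparison alike, Rhoj was at 0.41 in M3cKO PNX. With endothelial cells gated per cell Il6 was at −0.70 in WT PNX against sham. Without the stress-led cluster the stress median was −0.057 in M3cKO PNX, since that cluster is chosen by these genes.

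At a minimum of 20 CPM 232 genes were higher in WT PNX than in sham, 192 lower in M3cKO PNX, and 14 higher and 12 lower in Foxo1cKO PNX. At 100 CPM the first 2 were 49 and 48, 3 were higher in Foxo1cKO PNX, and the knockouts' correlation was 0.164; these settings change how many genes are counted. With every cell weighing the same 3 genes were higher in Foxo1cKO PNX, without genes high in non-endothelial classes 3 were lower, and with sham in place of WT PNX 58 were lower in M3cKO PNX.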

Other observations

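The genes and tests in this part were all chosen after their values were seen. The circadian clock genes Per2 and Arntl set M3cKO PNX endothelium apart from the other libraries. Per2 was at 40.7 CPM in M3cKO PNX and at 3.80, 2.82 and 2.40 in sham, WT PNX and Foxo1cKO PNX, while Arntl, which peaks in the opposite phase, was at 3.46 against 23.8, 24 and 21.6. The lung fibroblasts of the same library shared this, with Dbp at 128 CPM against 9.56, 4.40 and 11.9 and Arntl at 2.51 against 19.1, 31.9 and 25.3. These fibroblasts numbered 53 in M3cKO PNX against 68, 154 and 119, so their low values, Arntl in M3cKO PNX among them, rest on few UMIs. Fkbp5, a gene induced by glucocorticoids, was at 84.1 CPM in M3cKO PNX endothelium against 13.6, 23.7 and 22.5, and in fibroblasts at 223 against 9.56, 19.8 and 16.4. The time of day of collection is not given in the sources used here.

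Sex transcripts divided more than Foxo1 within the libraries that held both sexes. H2-Eb1 was at 12.3 CPM in male-type and 79.1 in female-type cells of WT PNX, and at 68.7 and 10.8 in Foxo1cKO PNX, the opposite order. Rsad2, an antiviral interferon-induced gene, was at 97.8 CPM in male-type and 27.6 in female-type Foxo1cKO PNX cells. At least 2-fold higher in male-type than in female-type cells were 19 genes in WT PNX and 48 in Foxo1cKO PNX, and 14 and 6 were lower.

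Among single-library patterns, 32 endothelial genes were at least 2-fold higher in all 3 PNX libraries than in sham and 9 lower. M3cKO PNX alone was at least 2-fold above the other libraries in 32 genes and below them in 14. WT PNX alone stood above in 4 and below in 1, and Foxo1cKO PNX alone above in 3 and below in 1. In the sham library 234 of 7617 barcodes carried 1 of 3 sequences in the last of the 3 barcode blocks that were nearly absent elsewhere, with 0 of 9266 barcodes in WT PNX, 1 of 9080 in M3cKO PNX and 1 of 8720 in Foxo1cKO PNX.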
